A study of Mus musculus with 4 samples.

How the data were processed

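RNA was measured in mouse bone marrow progenitors of the LSK surface type (no lineage markers, Sca-1 and c-Kit present), a population that holds the hematopoietic stem cells. The cells carried Evi-1 alleles flanked by loxP sites and received a retrovirus with GFP alone or with Cre recombinase and GFP. GFP-positive cells were sorted, and their RNA was amplified and biotin-labelled with a NuGEN Ovation kit, per the labels' protocols, and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. There were 2 arrays of GFP control cells and 2 arrays of Cre-GFP cells. The labels speak of 2 independent experiments but do not tie the array numbers to them. Which animals each array came from is not stated either, so p-values here measure the spread between these arrays, which may be partly technical.

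The deposited values were linear signal intensities, 1 for each probe set and array, and the submitters' processing notes name GCOS, the Affymetrix operating software. The signal algorithm, the scaling target and the software version are not given in the sources used here. The table held 45101 probe sets. The 64 control probe sets were left out. Of the other 45037, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. Of those with 1 symbol, 34741 were matched by Entrez number to a RefSeq gene table of GRCm38.p6, and 0 symbols changed. Probe sets with several symbols or none were tested but not named as genes. No genome build is given for the array values, so no coordinates are printed.

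The 2%-trimmed means of the arrays differed by 37.3%, over the limit of 5% set before the data were examined. The values were therefore converted to log2(signal + 16) and quantile-normalised. The pseudocount of 16 shrinks differences of dim probe sets, so their fold changes are understated. Probe sets with a mean log2 value at or above the median of all probe sets were tested. This left 22519 probe sets, of which 19006 had 1 symbol, 566 several and 2947 none, and the level at that limit was 4.39, or a signal of about 5.02. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), without a covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom per probe set and 13.8 after the prior was added. A log2 difference is Cre-GFP minus GFP control throughout, and SE is its moderated standard error. With 2 arrays against 2, a permutation test cannot give a p below 0.333. The number of arrays limits the precision of every value.

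For gene lists, each gene was represented by its tested probe set with the highest mean level, which gave 10326 genes. The 24 lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over all 24. Camera compares a list with all other genes. The lists were repeated with the correlation estimated per list, a version whose test has only 2 residual degrees of freedom here, and with fry, which asks whether a list's genes move, on balance, in a single direction. The lists, the tests and the alternatives were chosen before the data were examined. The alternatives were pseudocounts of 1 and 64, the values as deposited, arrays centred on their medians, the array number as a block, no intensity trend, a robust prior, no filter, the top 30% of probe sets, a minimum log2 change of 0.5, averaging over the probe sets of a gene, and leaving out each array.

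Named genes followed a rule. Mecom was always named. In each direction the 12 largest log2 differences past the threshold were named, if the probe set had 1 symbol and the arrays of the groups did not overlap. Where fewer than 12 qualified, probe sets with the smallest p and a log2 difference of at least 1 without overlap were added and are stated as not passing. For each list past the threshold the 3 members with the smallest p in its direction and the 1 with the smallest p in the other direction were named, and for every other list the 1 member with the smallest p. Other tested probe sets of a named gene that went the other way are given. Pf4, Itga2b, Esam, Cdkn1a, Skil and Tgfb1 fall outside this rule and were chosen after their values were seen.

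The procedure was tested on simulated data for the comparison of Cre-GFP with GFP control, with 200 changed probe sets among 22519 in each of 20 simulations. It recovered 19.6% of changes of 0.5 on the log2 scale, 86.1% of changes of 1 and 100% of changes of 2. Of its calls, 4.11% were unchanged probe sets. A megakaryocyte list shifted by -0.2 was called in 100% of simulations, and 0.3 other lists were called per simulation on average. The simulated probe sets varied independently of each other and held no array effects, so these rates may be too favourable for the real arrays. Estimated inter-gene correlations of the real lists reached 0.226. In the closing section, gene sets were set against 10000 random sets matched on mean level in 20 bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.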

Results

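Gene expression was compared between LSK cells with floxed Evi-1 alleles that had received Cre-GFP and those that had received GFP alone. The aim was to find transcripts that differ when the Evi-1 gene (symbol Mecom), a zinc finger transcription factor, is targeted for deletion. Only the Cre-GFP cells received Cre, and no array analysed here holds Cre in cells without the floxed alleles. Every difference below may therefore come from Cre itself as well as from loss of Evi-1. The trimmed mean signal was 60.5 and 65.6 on the GFP control arrays and 57.5 and 47.8 on the Cre-GFP arrays, so Cre-GFP replicate 2 was the dimmest. The spiked hybridisation controls had geometric means of 2259, 2436, 2239 and 2057 in the same order. They include probe sets for the phage P1 cre gene, which Cre RNA of the Cre-GFP cells could also reach. Their signal may therefore depend partly on the cells. The ratio of 3' to 5' Gapdh signal, a measure of RNA length, was 1.53 and 1.40 in GFP control and 1.33 and 1.53 in Cre-GFP. Across probe sets the arrays correlated at 0.988 to 0.993 (Pearson), and the values across probe sets are not independent replicates. The first principal component held 44.0% of the variance and separated the groups. By correlation, however, the Cre-GFP arrays were not set apart. They were at least as close to GFP control replicate 2 (0.991 and 0.9894, Pearson) as to each other (0.9893).

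**Figure D1:**
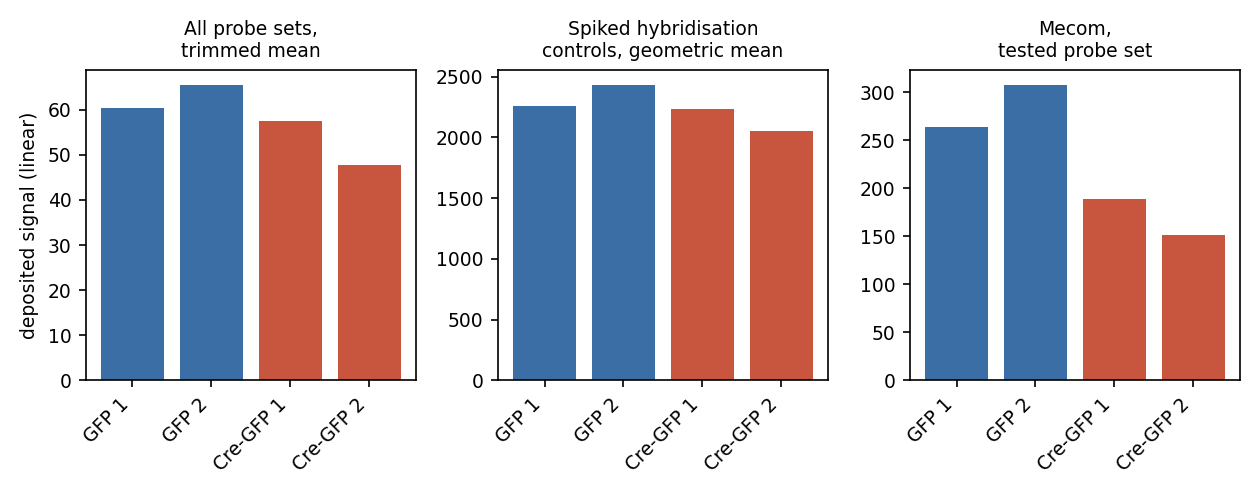
Bars give deposited linear signal on each of the 4 arrays for the trimmed mean over all probe sets, the geometric mean of the spiked hybridisation controls and the tested Mecom probe set; each panel has its own axis from 0. Cre-GFP replicate 2 has the lowest bar in each panel, and Mecom signal is 264 and 308 on the GFP control arrays against 189 and 151 on the Cre-GFP arrays.

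Mecom signal was lower on both Cre-GFP arrays than on both GFP control arrays, but the difference did not pass the threshold. The tested Mecom probe set read 286 ± 31.5 in GFP control (SD, n = 2) and 170 ± 26.6 in Cre-GFP (SD, n = 2). After normalization the log2 difference was -0.42 (SE 0.09), a ratio of 0.748, with a limma adjusted p = 0.685 over all probe sets and 0.174 over the tested probe sets. With arrays centred on their medians the limma adjusted p was 0.00974, against 0.302 to 0.962 under the other alternatives. The remaining 2 Mecom probe sets read 0.125 to 5.31 on every array, near background. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so these values are a limited check of the labels.

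Among individual genes, Cre-GFP cells had less RNA for Mycn, a Myc family transcription factor, for Itgb3, the integrin beta 3 subunit of platelets, and for Smad3, a transducer of TGF-beta signals. They had more RNA for Trp53inp1, a p53-induced nuclear protein, for Tob1, an antiproliferative protein, and for Chka, choline kinase alpha. Of 22519 probe sets, 32 passed the limma threshold, 14 higher and 18 lower in Cre-GFP, and this count depended on the processing. None passed in limma without an intensity trend, without a filter or with the probe sets of a gene averaged, while 2 higher and 139 lower passed with the values as deposited and 263 with the array number as a block. The folds were 1.47 to 2.02 among the higher probe sets and 1.38 to 2.34 among the lower ones. The 2.34 belongs to Rpl37a, whose Cre-GFP signals of 8.66 and 4.96 were near background, so its size is set by the pseudocount. All 32 had both Cre-GFP arrays on the same side of both GFP control arrays.

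Mycn had the smallest limma adjusted p, 0.0047, and fell by 0.60 on the log2 scale (SE 0.06), from signals of 2483 and 2635 to 1627 and 1388. Pmepa1, a TGF-beta-induced inhibitor of Smad signalling, fell by 0.83 (SE 0.12), while another, dim probe set of the gene stood at 0.04. Smad3 fell by 0.68 (SE 0.11). Itgb3 fell by 0.66 (SE 0.10), Rab27b, a GTPase of granule secretion, by 0.60 (SE 0.10), and Ms4a2, a subunit of the high-affinity IgE receptor, by 0.84 (SE 0.15). The limma adjusted p of these 5 genes was 0.0241 to 0.0437. Podxl, a CD34-related sialomucin, fell by 0.83 and Gucy1a1, a subunit of soluble guanylate cyclase, by 0.94. Dlk1, a Notch-related surface protein, fell by 1.08. Dimmer probe sets of Mycn, Itgb3 and Gucy1a1 did not pass, at -0.17 (SE 0.16), -0.05 (SE 0.17) and -0.11 (SE 0.17). Those of Rab27b stood at -0.34 and -0.40, that of Ms4a2 at -0.46 and that of Dlk1 at -0.55, and did not pass. Rilpl1 fell by 0.75 and by 0.83 with separate probe sets. The log2 differences of Rpl37a and Smarcb1 were -1.22 and -1.06, each on a probe set of the cross-hybridising class. Other probe sets of Rpl37a stood at -0.08 and -0.11, and that of Smarcb1 stood at -0.03, so the genes' own levels remain uncertain.

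Among the higher genes, Rbm39, a splicing factor, rose by 0.70 (SE 0.12) on 1 probe set of medium level. Its 11 other probe sets were all above 0 and did not pass, 9 of them at 0.28 to 0.72 and the 2 brightest at 0.02 (SE 0.06) and 0.05 (SE 0.07). Zfp207, a kinetochore and RNA-associated zinc finger protein, rose by 0.85 (SE 0.14) on 1 probe set. Its other probe sets did not pass, and stood at 0.59 (SE 0.12), 0.56 (SE 0.11), 0.23 (SE 0.10) on the brightest, 0.17 (SE 0.10) and, on a dim probe set, -0.08. Pan3, a subunit of a poly(A) nuclease, rose by 0.80 (SE 0.14) on its dimmest tested probe set, and its 2 brighter probe sets stood at 0.17 each and did not pass. Tob1 rose by 0.81 (SE 0.14), Chka by 0.82 (SE 0.12) and Trp53inp1 by 0.60 (SE 0.09). The limma adjusted p of these 6 genes was 0.0241 to 0.0448. Impact, an inhibitor of the Gcn2 pathway, rose by 0.78, Hsdl2 by 0.73 and Pdcl, a phosducin-like protein, by 0.55. Chka, Trp53inp1, Impact, Hsdl2 and Pdcl each passed only on their brightest probe set. Dimmer probe sets stood at 0.22 (SE 0.18) and 0.25 (SE 0.15) for Chka and 0.19 (SE 0.17) for Trp53inp1. Those of Impact, Hsdl2 and Pdcl stood at 0.20 (SE 0.18), 0.26 (SE 0.15) and 0.18 (SE 0.16). For the sorting nexin Snx10 the log2 difference was 0.65 on a probe set of the cross-hybridising class, and the brighter Snx10 probe set stood at 0.07, so the level of that gene remains uncertain. Of the 14 higher probe sets 4 had no gene symbol, against 0 of the 18 lower. Slc35a5 (1.06, limma adjusted p = 0.134) and Tbca (1.01, limma adjusted p = 0.094) did not pass, and other Tbca probe sets stood at -0.14 and -0.06. Slc35a5 read 66.7 and 65.3 in GFP control but 210 and 73.7 in Cre-GFP, so its size rested mainly on Cre-GFP replicate 1. The Tbca probe set is of the cross-hybridising class. Its GFP control signals of 9.61 and 7.45 were near background, so its size depends on the pseudocount.

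The number of probe sets passing also moved with each array left out. In limma 2 passed without GFP control replicate 1, of which 1, Mycn, was among the 32, against 46 without GFP control replicate 2, 135 without Cre-GFP replicate 1 and 113 without Cre-GFP replicate 2. With all arrays 2209 probe sets had an unadjusted p under 0.05, against 1126 by chance.

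**Figure D2:**
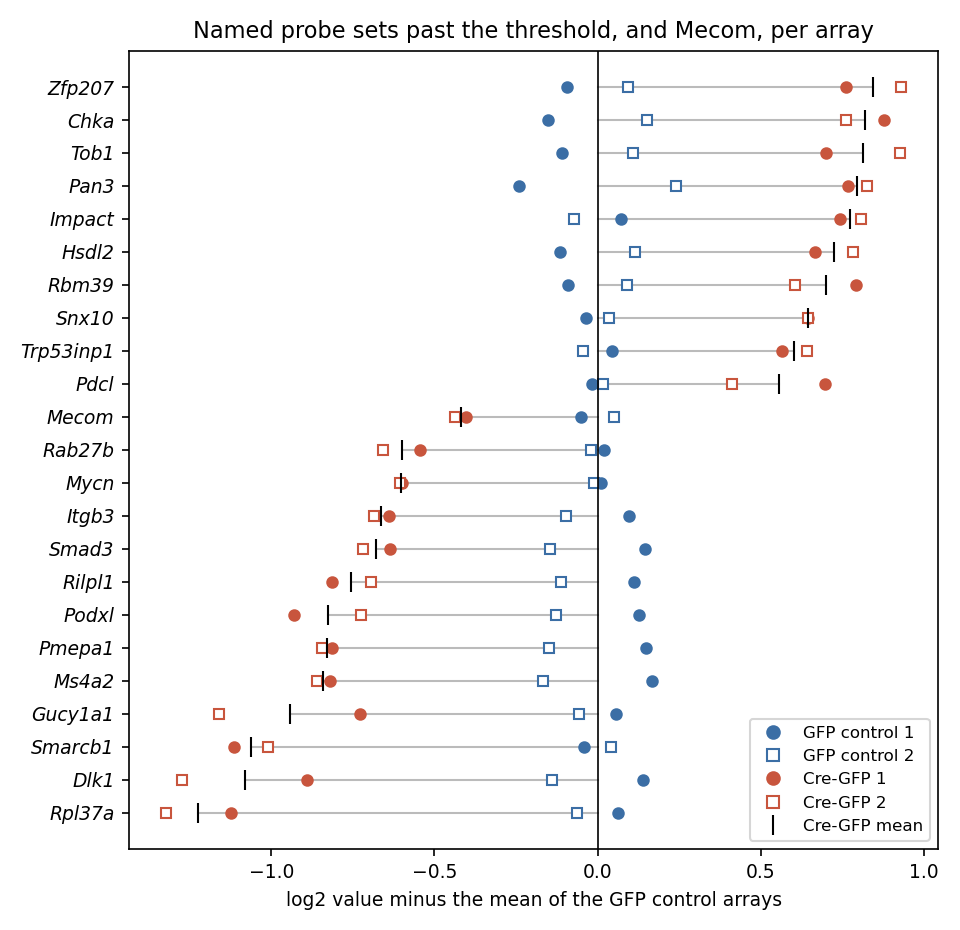
Log2 value on each array minus the mean of the GFP control arrays, for the named probe sets past the limma threshold and for Mecom, which did not pass; circles are replicate 1, squares replicate 2, and the black bar is the Cre-GFP mean. For every gene shown both Cre-GFP arrays lie on the same side of both GFP control arrays, which the naming rule required of the passing genes. The differences run from -1.22 for Rpl37a to 0.85 for Zfp207.

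By size alone, 7 probe sets differed at least 2-fold without overlap between the groups, 3 higher and 4 lower in Cre-GFP. This count was 458 with a pseudocount of 1, 0 with a pseudocount of 64 and up to 26 with an array left out. With the pseudocount of 16, each of the other 2 ways of splitting the arrays gave 3. At any size, 40.0% of the tested probe sets did not overlap between the groups, against 27.5% and 32.2% in the other splits and about 1 in 3 by chance. Without ties, a probe set is free of overlap in exactly 1 of the 3 splits. A higher share in one split thus lowers the others, which are no independent baseline.

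Among the gene lists, camera at its preset correlation called megakaryocyte genes lower in Cre-GFP cells, along with markers of mast cells and related granulocytes and of hematopoietic stem cells, and immediate early genes higher, but no list passed with an estimated correlation. Of 24 lists 8 passed at the preset correlation, 5 lower and 3 higher, and with fry only the stem cell list did (adjusted p = 0.0276). The estimated correlation was 0.226 for oxidative phosphorylation, 0.182 for mast cell, 0.141 for ribosomal and 0.045 for CDK inhibitor and quiescence genes. It was -0.029 for megakaryocyte, -0.026 for immediate early, -0.027 for p53 and -0.022 for stem cell genes, under the preset 0.01. These last lists lost their pass in a test with 2 residual degrees of freedom, not through a higher correlation.

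The megakaryocyte list, with surface receptors and granule proteins of the platelet lineage, fell with a median log2 difference of -0.19 (camera adjusted p = 3.18e-05, and adjusted p = 0.453 with an estimated correlation). The median was -0.34 with a pseudocount of 1 and in the top 30% of probe sets. It was -0.43 with the values as deposited, where all tested probe sets had a median of -0.183. Of 30 members 24 were lower and 6 higher. Itgb3 and Rab27b passed over all probe sets. Adjusted over the list alone, 7 were lower, among them the thrombin receptor F2r at -0.45 (SE 0.08), Pf4, the chemokine platelet factor 4, at -0.42 (SE 0.09) and Itga2b, the partner of Itgb3, at -0.66 (SE 0.16), and 1 was higher, the transcription factor Fli1 at 0.25 (SE 0.09).

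The mast cell, basophil and eosinophil list fell with a median of -0.22 (camera adjusted p = 0.00538, and adjusted p = 0.539 with an estimated correlation), with 13 of 20 members lower. Ms4a2 passed over all probe sets, and 6 members were lower adjusted over the list alone. Gzmb, granzyme B, stood at -1.06 (SE 0.19), Slc18a2, a vesicular monoamine transporter, at -0.52 (SE 0.13), and Tpsb2, a mast cell tryptase near background, at 0.44 (SE 0.20). Without GFP control replicate 1 the median of this list was -0.03 and its camera adjusted p 0.214, and without Cre-GFP replicate 2 the median was -0.12. It was -0.09 without a filter, -0.11 with a pseudocount of 64 and -0.41 with the values as deposited, against -0.183 over all tested probe sets there.

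The stem cell marker list fell with a median of -0.13 (camera adjusted p = 0.0141, and adjusted p = 0.453 with an estimated correlation), with 23 of 34 members lower. Mycn passed over all probe sets, and 4 members were lower adjusted over the list alone. They included the transcription factors Tal1 at -0.53 (SE 0.13) and Gata2 at -0.27 (SE 0.07) and the adhesion molecule Esam at -0.82 (SE 0.23). Rarb, a retinoic acid receptor, stood at 0.34 (SE 0.17). The camera adjusted p was 0.0538 without GFP control replicate 2 and 0.0699 without an intensity trend. The median was -0.08 with a pseudocount of 64 and without a filter. With the values as deposited it was -0.35, against -0.183 over all tested probe sets.

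Immediate early and AP-1 genes, which respond to stimulation within minutes and also to cell handling, rose with a median of 0.10 (camera adjusted p = 6.54e-04, and adjusted p = 0.453 with an estimated correlation). Of 32 members 19 were higher. None passed over all probe sets, where 7 members had an unadjusted p under 0.05 in limma, and 4 were higher adjusted over the list alone. Fos stood at 0.73 (SE 0.13), Jun at 0.39 (SE 0.08), the phosphatase Dusp1 at 0.48 (SE 0.10) and Dusp2 at -0.31 (SE 0.17). The median of the list was 0.04 without Cre-GFP replicate 1 and 0.06 without GFP control replicate 2, and the list passed in camera with any array left out.

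The p53 target list was called higher, with a median of 0.03 and a mean of 0.07 (camera adjusted p = 0.0141, and adjusted p = 0.453 with an estimated correlation). Of 35 members 19 were higher and 16 lower. Trp53inp1 passed over all probe sets, and 3 were higher adjusted over the list alone, with Zmat3 at 0.79 (SE 0.15) and cyclin G1 (Ccng1) at 0.47 (SE 0.10), another probe set of which stood at -0.02. Cdkn1a, the p21 cell cycle inhibitor, stood at -0.02 (SE 0.11) and Bbc3, an apoptosis inducer, at -0.31 (SE 0.17). The camera adjusted p was 0.0541 without GFP control replicate 2 and 0.0519 without a filter, where the median was 0.01. The median was 0.12 without Cre-GFP replicate 1 and 0.07 in the top 30% of probe sets and on the mean of probe sets.

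The list of CDK inhibitors and quiescence genes was called higher at a median of 0.06 (camera adjusted p = 0.0463, and adjusted p = 0.539 with an estimated correlation), with 15 of 26 members higher. The list as written also holds the cell cycle drivers Ccnd1, Ccnd2, Ccnd3, Cdk4 and Cdk6, so its direction has no single meaning. It shares Klf2, Klf4, Klf6, Nr4a1, Nr4a2 and Btg2 with the immediate early list. Cdkn1a, Gadd45a and Btg2 are shared with the p53 list, so the 3 higher lists are not independent results. Tob1 passed over all probe sets and was the only member past the threshold adjusted over the list alone. Btg2, a relative of Tob1, stood at 0.33 (SE 0.17), Rb1, the retinoblastoma protein, at 0.21 (SE 0.13) and Ccnd3, cyclin D3, at -0.29 (SE 0.16). This call was lost when any array was left out, with a camera adjusted p from 0.0505 to 0.261, and with centred arrays (0.107), no intensity trend (0.0869), no filter (0.153) and the top 30% of probe sets (0.0658), and its median was 0.03 without GFP control replicate 1 and 0.08 without GFP control replicate 2. With the values as deposited the median of all tested probe sets was -0.183. The medians of the 3 higher lists there were -0.07 for immediate early genes, -0.15 for p53 targets and -0.15 for CDK inhibitors and quiescence genes. Each lay above that shift, and the last list no longer passed.

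Oxidative phosphorylation genes were called lower by a small amount, a median of -0.06, with 52 of 62 members lower (camera adjusted p = 0.0158, and adjusted p = 0.676 with an estimated correlation). None passed over all probe sets or adjusted over the list alone, and 5 had an unadjusted p under 0.05 in limma, all lower. Cox5b stood at -0.31 (SE 0.10), Ndufv1 at -0.39 (SE 0.13), Atp5c1 at -0.21 (SE 0.07) and Cox5a at 0.13 (SE 0.08), while another Cox5a probe set stood at -0.00474. Without GFP control replicate 1 or Cre-GFP replicate 1 the camera adjusted p was 0.269 and 0.483, and without an intensity trend or on the mean of probe sets it was 0.121 and 0.0654. The median was -0.04 without Cre-GFP replicate 1 and -0.11 without either GFP control replicate 2 or Cre-GFP replicate 2. It was -0.12 with centred arrays and -0.32 with the values as deposited, against -0.183 over all tested probe sets there.

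Ribosomal protein genes had a median of -0.06, with 29 of 37 members lower (camera adjusted p = 0.023, and adjusted p = 0.655 with an estimated correlation), but the median turned to 0.02 with arrays centred on their medians. None passed over all probe sets, 6 had an unadjusted p under 0.05 in limma, and 2 were lower adjusted over the list alone, Rpl19 at -0.29 (SE 0.07) and Rpl35 at -0.26 (SE 0.07). Rpl8 stood at -0.20 (SE 0.07) and Rps25 at 0.19 (SE 0.10), and another, dim Rpl35 probe set at 0.04. Without GFP control replicate 1 or Cre-GFP replicate 1 the camera adjusted p was 0.261 and 0.144, with medians of -0.03 and -0.05. With all arrays the camera adjusted p was 0.614 without an intensity trend and 0.187 on the mean of probe sets. With the values as deposited it was 0.675, and the median of -0.18 was that of all tested probe sets there (-0.183).

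The other 16 lists did not pass. TGF-beta and BMP genes had a median of -0.06 over 35 members (camera adjusted p = 0.139). This rested on the control arrays, with a median of -0.11 and a camera adjusted p of 0.00731 without GFP control replicate 1, and a median of -0.00441 without GFP control replicate 2. Pmepa1 and Smad3 passed over all probe sets, and 4 members were lower adjusted over the list alone, including Skil, a Smad repressor, at -0.33 and Tgfb1 at -0.60. The list of genes linked to EVI1 in the literature had a median of -0.04 over 27 members (camera adjusted p = 0.684). Its median was 0.05 without Cre-GFP replicate 1 and -0.08 without GFP control replicate 2. Smad3 passed over all probe sets, and adjusted over the list alone 5 were lower and 3 higher. The camera adjusted p was 0.0603 for monocyte genes, with Vcan at 0.33, 0.0978 for interferon response genes, with Cxcl10 at -0.69, 0.0992 for vascular genes, with Tal1 at -0.53, and 0.125 for erythroid genes, with carbonic anhydrase Car2 at -0.44. Interferon response genes passed in camera without GFP control replicate 2 (adjusted p = 0.0349), without a filter (0.0296) and with the array number as a block (0.0468). Monocyte genes passed in camera in the top 30% of probe sets (adjusted p = 0.0458) and on the mean of probe sets (0.0358). Adjusted over the list alone, these 4 lists had 0, 1, 2 and 2 members past the threshold, and over all probe sets 0 in each, with 4, 3, 2 and 3 members at an unadjusted p under 0.05 in limma.

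In the remaining lists the camera adjusted p was 0.214 for granulocyte genes, 0.36 for glycolysis and hypoxia, 0.446 for the Hox and Meis family, 0.615 for dendritic cell genes, 0.756 for cytokine receptors and adhesion, 0.83 for mitosis, 0.864 for stromal genes and for lymphoid genes, and 0.881 for apoptosis regulators and for S phase genes. Members with the smallest p were Nkg7, a cytotoxic granule protein, at -0.37, Ldha, lactate dehydrogenase A, at -0.20, Hoxa10 at -0.26, Cd83 at -0.52, Itgb3, which passed over all probe sets, among the receptors, Aurka, the Aurora A kinase, at -0.44, Mmp14 at -0.47, Fadd at -0.73 and Pcna, the replication clamp, at -0.19. The Fadd signals were 29.5 and 69.5 in GFP control and 17.5 and 16.9 in Cre-GFP, so its size rested mainly on GFP control replicate 2. Another Fadd probe set stood at 0.31. Nkg7 was also the lead member among lymphoid genes. Adjusted over the list alone 1 member was lower in each of the dendritic, receptor and lymphoid lists and 0 in the other lists named here, where the counts at an unadjusted p under 0.05 in limma were 0 to 4.

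**Figure D3:**
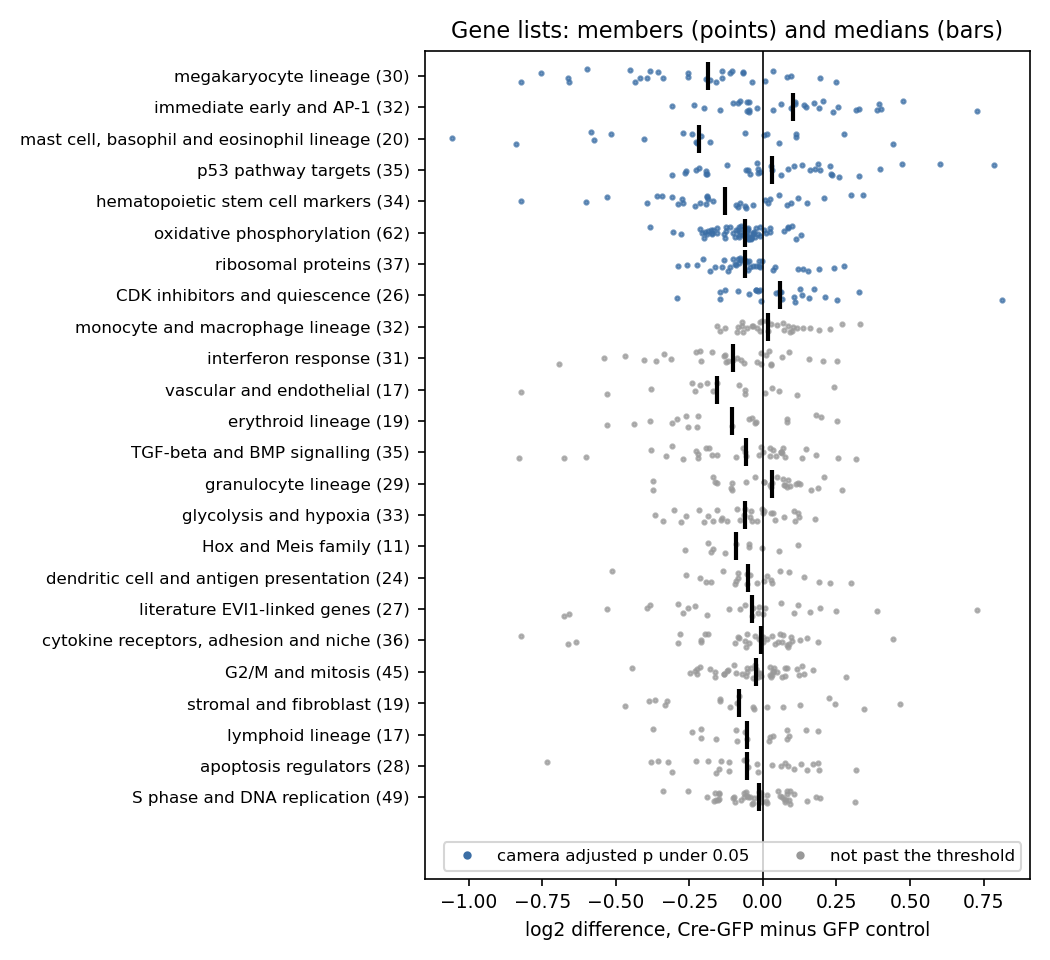
Log2 difference (Cre-GFP minus GFP control) of each tested member of the 24 gene lists, with the number of members in parentheses; points are genes, black bars are list medians, and blue marks a camera adjusted p under the threshold with the preset correlation. Medians of the called lists run from -0.22 for mast cell genes to 0.10 for immediate early genes, and all 24 lists hold members on both sides of 0.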

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

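The alternatives here were planned before the data were examined. The direction of Mecom and of all named passing genes held in every alternative run. This says little, because passing genes were named only if the groups did not overlap, which all but fixes the sign. The groups did not overlap for Mecom either. The 32 calls were shared with the array number as a block, with arrays centred and with a robust prior. Counts moved more, and the cause was not tested except where stated.

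In limma, a pseudocount of 1 gave 14 calls (5 higher, 9 lower), the values as deposited 141 (2 higher, 139 lower, against 14 and 18), arrays centred on their medians 79 (28 higher, 51 lower) and a robust prior 54 (29 higher). Counts were 0, with 0 higher and 0 lower, without an intensity trend (2030 probe sets at an unadjusted p under 0.05), without a filter (3266), with a minimum log2 change of 0.5 by treat (40) and with the probe sets of a gene averaged (1006). Leaving out each array gave 2 to 135 calls, 1 to 62 higher and 1 to 79 lower: 2 without GFP control replicate 1, 46 without GFP control replicate 2, 135 without Cre-GFP replicate 1 and 113 without Cre-GFP replicate 2. A fit that keeps a single array in a group assumes that it varies like the other group.

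The 2-fold count was 458 with a pseudocount of 1 and 0 with 64, which follows from how the pseudocount widens or shrinks differences of dim probe sets, 18 as deposited and 7 to 26 with an array left out. Mecom passed in limma only with centred arrays (-0.50). With the array number as a replicate block 263 probe sets passed (142 higher, 121 lower), Mecom stayed at -0.42 and 9 lists passed. The labels speak of 2 experiments without tying the array numbers to them, so the number was not a covariate in the main fit. Whether it pairs the arrays remains unresolved. The deviations of arrays with the same number correlated at -0.0639. Lists past the threshold were 4 without a trend, 0 with an estimated correlation, 1 with fry and 5 to 7 with an array left out. The ribosomal list turned to 0.0187 with centred arrays (adjusted p = 0.396). Over 15 alternatives per list, medians ran from -0.43 to -0.14 for megakaryocyte genes (13 past the threshold), -0.07 to 0.15 for immediate early genes (13), -0.41 to -0.03 for mast cell genes (12), -0.35 to -0.08 for stem cell markers (12), -0.15 to 0.12 for p53 targets (11), -0.32 to -0.04 for oxidative phosphorylation (9), -0.18 to 0.02 for ribosomal proteins (7) and -0.15 to 0.08 for CDK inhibitors (4). Of the lists that did not pass, interferon response did in 3 alternatives, monocyte genes in 2, TGF-beta and BMP genes in 1 and the others in 0. Each called list had its lowest median with the values as deposited, where all tested probe sets had a median of -0.183. Signals near background, such as that of Tpsb2, limit what the arrays resolve.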

Other observations

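Tests of the dim array, of Cre itself and of the other splits were chosen only after the result was seen, as were the smaller megakaryocyte subsets, the intron test without Malat1, the median test of the p53 list and the reading of the gap between arrays given here. The decision to set aside the planned bound for the share of cells with megakaryocyte transcripts was also made after its result was seen.

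Probe sets without a gene symbol were higher in Cre-GFP cells. Of 2947 tested, 321 were higher and 83 lower at an unadjusted p under 0.05 in limma, against 803 and 957 of 19006 with 1 symbol. Their median of 0.06325 lay above 10000 sets of named probe sets matched on level (-0.0267 to -0.0113), which argues against a level-dependent bias of the normalization. The gap of 0.05457 between the groups exceeded the larger difference within a group, 0.0328, and so met the bound set in advance against array-to-array variation, but 2 arrays against 2 allow only 3 splits, so that explanation cannot be told apart from a group effect. More incompletely spliced RNA may contribute, but the test cannot decide it. Genes with retained introns were listed before the test but after Rbm39 and Zfp207 had been seen, and those were left out. The 119 secondary probe sets of 37 coding genes on the list had a median of 0.07207. This lay above the upper end of the central 95% of matched secondary probe sets, 0.0373. The brightest probe sets of those genes had 0.0196. Random sets did not keep the probe sets of a gene together, so that range may be too narrow. Where the probe sets lie relative to introns is not given in the sources used here. The planned list also held 6 probe sets of Malat1, a largely unspliced noncoding RNA that does not measure splicing, and had the same median with them.

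Megakaryocyte genes were called lower in camera, but not with an estimated correlation (adjusted p = 0.453 with an estimated correlation) or with fry (adjusted p = 0.155). Their median was -0.2487 without Cre-GFP replicate 2, which argues against that dim array as the source, and the median of -0.1877 with all arrays lay below the lower end of the central 95% of level-matched gene sets, -0.0997. A smaller share of cells with megakaryocyte transcripts could also lower the list. The planned test of this, Cochran's Q over all 30 members against a chi-square distribution, gave p = 1.934e-20, so members moved apart by more than their errors, as against a common shift; but 18 members are also expressed in other cells and 13 lie under a log2 level of 6, where the pseudocount shrinks differences, so that bound was wrong for this list. The same chi-square test of Q over the 12 members taken as restricted gave p = 1.10e-06 and over the 5 brighter of them p = 0.158. That smaller subset was picked after its members' values were seen and so has no weight. Whether the 12 are expressed in other LSK cells was not tested. The share of cells cannot be told apart from a change per cell.

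The p53 target list was called higher in camera, but not with an estimated correlation (adjusted p = 0.453 with an estimated correlation) or with fry (adjusted p = 0.198). Its mean was 0.07289 without Cre-GFP replicate 2, which argues against that array as the source. The mean of 0.07139 lay above the upper end of the central 95% of level-matched gene sets, 0.0312, but the median of 0.03128 lay inside the central 95% for medians, whose upper end was 0.0401, so the tables argue against a level-dependent bias for the mean and leave it open for the median. Cre itself, which can damage DNA, could raise the list as well as loss of Evi-1, and these cannot be told apart because no array analysed here holds Cre in cells without the floxed alleles.

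For the probe sets passing in limma, 1 of the 3 splits of the 4 arrays gave as many as 32, the real split, and the highest of the others gave 0, with 885 and 456 probe sets at an unadjusted p under 0.05. With 3 splits no share under 0.05 can be reached.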
